A study of Drosophila melanogaster with 3 samples.

How the data were processed

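Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster embryos of the w1118 strain aged 13 to 16 h. Chromatin was fixed with 1.8% formaldehyde and sonicated, per the labels' protocols. The series holds 3 libraries, made with a mouse anti-Grh antibody, a rabbit anti-Grh antibody and rabbit IgG. There is 1 library per antibody, so no replicate spread can be given. The IgG library was not analysed here.

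Reads were aligned with Bowtie to the dm3 genome build, per the submitters' processing notes. The Bowtie version, the peak caller, its thresholds and its use of the IgG control are not given in the sources used here. The authors deposited 1 peak list per anti-Grh library, so the lists were not made from pooled samples. Each row holds a chromosome, a 2 bp interval, a name with a number and a rank, and a score, per the file headers and rows. The unit of the deposited score is not stated. Its lowest value was 2.0 in both lists. It was used to order peaks and compare medians within a list, and to correlate paired peaks between the lists. Scores of the 2 lists need not be on 1 scale. The numbering in the deposited names is a second order, of unstated basis. Its Spearman correlation with the score order was 0.43 in the mouse list and 0.50 in the rabbit list. With the deposited rank it was 0.89 in the mouse list and 0.96 in the rabbit list. Because each peak is a point, peaks are named here by the first base of their interval, counted from 1, in dm3 coordinates. Read depth is unknown, so the effect of depth on the length of each list cannot be removed.

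The planned definition of a shared peak, an overlap of at least 1 bp between deposited intervals, would ask 2 bp points to coincide. Peaks were instead called shared, or matched, where the first bases lay within 250 bp of each other, a setting that was also planned. Chance sharing was measured with 1000 circular shifts, in which the mouse list was moved by a random offset along each chromosome. The smallest p that these shifts can give is 0.001. Chromosome lengths were taken as the highest peak end in either list, which understates them by an amount not measured here. The understatement may be large on heterochromatic sequences with few peaks. Peaks per megabase rest on the same lengths. Scores of shared and unshared peaks were compared by a two-sided permutation test of the difference in medians with 100000 resamples (10000 for alternative settings). One-to-one pairs were peaks that were each other's nearest within 250 bp. The share of peaks on each arm was compared between lists by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 7 classes: 2L, 2R, 3L, 3R, 4, X and the heterochromatic sequences together. Crowding was measured as the variance-to-mean ratio of peaks per 100 kb window, against 1000 uniform placements. Intervals on shares are exact 95% binomial (Clopper-Pearson) intervals and cover counting error only. Peaks are not replicates, and neighbouring peaks are not independent. All p-values therefore describe these lists, not a spread between embryos or libraries. Groups of peaks were formed by chaining neighbours at gaps of up to 1 kb.

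Before the data were examined, the peaks to be named were fixed as the 10 pairs whose lower-placed member by score stood highest, the 5 highest-scoring unmatched peaks of each list, and the 5 windows of 100 kb with the most peaks in each list. Alternatives were other distances for sharing, the upper 50% of each list by score, lists of equal length, the major arms alone, another chance model and other windows. The comparisons of peak width and of genomic features, the Grh binding motif and gene lists near peaks were planned but not run. The intervals have 1 width, and no dm3 genome or annotation was used here; the gene table at hand is of another build, and positions were not converted. The overlap procedure was tested on simulated data made from the mouse list of 1638 peaks, with known shares placed near rabbit peaks. The number of matches above chance was estimated at 818 for 826 planted peaks (50%), 1489 for 1492 (90%) and -9 for 0. Planted peaks were placed well within 250 bp of a rabbit peak and so were matched by construction. The simulation thus tested only the correction for chance. The score test called 5 of 100 simulations with no difference and 50 of 50 with doubled scores. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.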

Results

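Grainy head (Grh) is a transcription factor of epithelia such as the epidermis and trachea, known for its part in forming and repairing the cuticle barrier. Its binding in embryos aged 13 to 16 h was mapped with antibodies raised in mouse and in rabbit, with rabbit IgG as the control immunoprecipitation. The mouse-antibody library gave 1638 peaks and the rabbit-antibody library 12158, a ratio of 7.42. Most peaks lay on the major arms, with 7 mouse and 29 rabbit peaks on the heterochromatic sequences of the dm3 build. Scores ranged from 2.0 to 31.5 in the mouse list (median 5.27) and from 2.0 to 233 in the rabbit list (median 5.98). The median gap between neighbouring peaks was 31434 bp in the mouse list and 2878 bp in the rabbit list. Each antibody had 1 library and read depths are unknown, so the difference in list length has no error.

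The use of 2 antibodies against 1 factor asks whether they marked the same places. They did so from the side of the mouse list: 1622 of its 1638 peaks, or 99% (exact 95% interval 98.4 to 99.4%), had a rabbit peak within 250 bp. Of the rabbit peaks, 1756 of 12158, or 14.4% (13.8 to 15.1%), had a mouse peak. Circular shifts of the mouse list matched 78.8 ± 9.51 mouse peaks (SD over 1000 shifts, highest 116), so the observed number was 20.6 times chance (one-sided permutation p = 0.001, the smallest the shifts allow). The centres coincided closely, with a median distance of 11 bp (quartiles 5 and 21 bp) against 5893 bp on average after shifting. Mouse peaks showed no displacement to either side of their rabbit partners, the median offset being 0 bp (quartiles -10 and 11 bp, mouse minus rabbit). With the rabbit list reduced to its 1638 highest-scoring peaks, 55.6% of mouse peaks were matched, with a median distance of 35 bp. With its first 1638 peaks in the authors' numbering, 25.2% were matched and the median distance was 12991 bp.

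**Figure D1:**
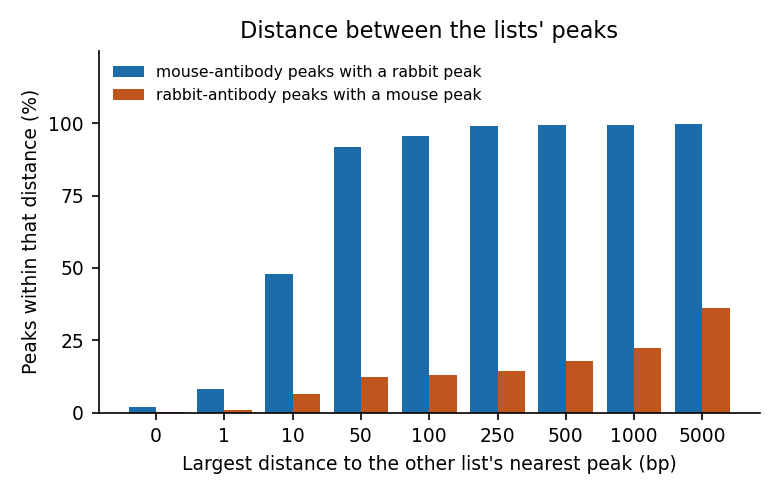
Bars give the percent of peaks (vertical axis) in the mouse-antibody list (blue) and the rabbit-antibody list (orange) whose nearest peak of the other list lies within the distance on the horizontal axis, in bp. At 50 bp 91.6% of mouse peaks but 12.3% of rabbit peaks had a partner.

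The strongest places common to both antibodies lay on 3L, X, 2L, 3R and 2R. The pair with the best worse order of score was on 3L, with the mouse peak at 20685800 and the rabbit peak 7 bp away, sixth in the mouse list by score (order 6, score 19.3) and of order 12 in the rabbit list (score 109). It was followed by a pair on 3L at 13021970, with a mouse score of 17.7 and a rabbit score of 90.5, and by one on X at 17207611, with scores of 21.9 and 89.3. The highest-scoring mouse peak of all, on 2L at 4030352 with a score of 31.5, had a rabbit peak 58 bp away with a score of 77.4. The remaining pairs among the first 10 were on 3R at 25667279, 2L at 18312155, 2R at 14765849, 3R at 23562204, 2L at 7009924 and 3R at 2567487. Their mouse scores ran from 12.4 to 22.2 and their rabbit scores from 68.7 to 76.5, and their centres lay at most 12 bp apart.

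Rabbit peaks with a mouse partner had higher scores than those without. Their median score was 15.7 (quartiles 10.7 and 22.8, 1756 peaks) against 5.45 (3.62 and 8.07, 10402 peaks), a ratio of 2.88 (permutation test, two-sided p = 1e-05, the smallest the resamples allow). The matched share fell from 56.3% (53.4 to 59.1%) in the top 10% of the rabbit list by score to 0.82% (0.40 to 1.51%) in the lowest 10%. Within the top 10% the share ran the other way, increasing as the score fell. Of the top 1% by score, 30 of 122 peaks had a mouse partner, or 24.6% (17.2 to 33.2%). The share was 49.6% (40.4 to 58.8%) between 1% and 2%, 56.7% (51.5 to 61.9%) between 2% and 5%, and 63.7% (59.7 to 67.5%) between 5% and 10%. Ordered by the authors' numbering, 8.20% (4.0 to 14.6%) of the first 1% were matched, 24.8% of the first 10% and 34.7% (32.0 to 37.5%) of the next 10%. In the mouse list the matched share was between 97.0% and 100% in each of 10 equal parts by score.

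**Figure D2:**
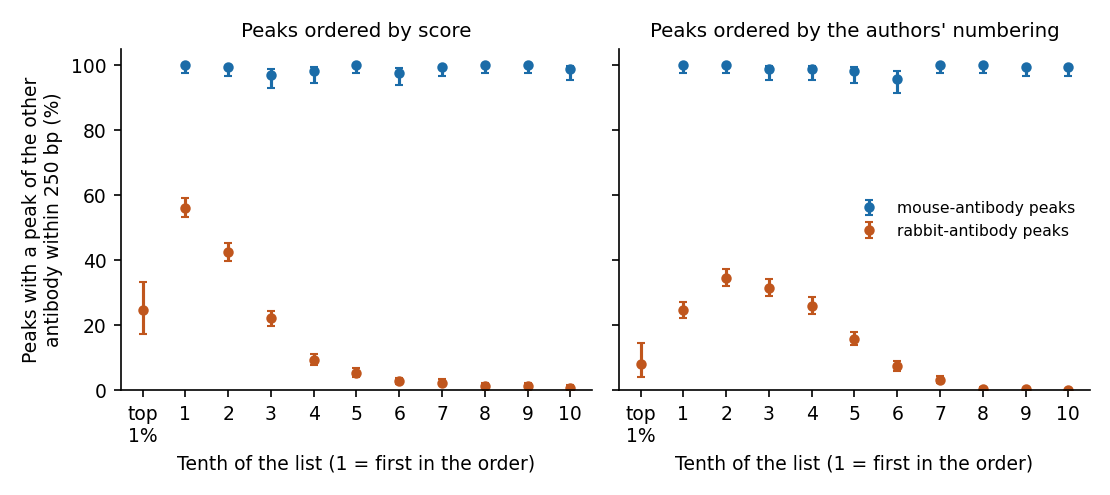
Percent of peaks with a peak of the other antibody within 250 bp (vertical axis) in each of 10 equal parts of the mouse list (blue) and the rabbit list (orange), ordered by score on the left and by the authors' numbering on the right; bars are exact 95% intervals. The first point of the rabbit list is its top 1% (24.6% by score, 8.20% by numbering), which lies below the first of the 10 parts.

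The 5 highest-scoring rabbit peaks were all without a mouse peak within 250 bp. The peak on 3R at 13442982 had the highest score, 233, and its nearest mouse peak was 3530 bp away. The peak on 3R at 796603, first in the authors' numbering, had a score of 213 and lay 39294 bp from the nearest mouse peak. The peak on 3L at 19133668 (score 211) lay 29758 bp away, that on 3RHet at 2349411 (score 145) 122020 bp away, and that on 2R at 4139212 (score 135) 21296 bp away. By contrast, the 5 highest-scoring mouse peaks, on 2L at 4030352 and 18312155, 3R at 25352459, X at 17207611 and 2R at 18821367, each had a rabbit peak within 58 bp.

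Of the 16 mouse peaks without a rabbit partner, 10 lay in 1 run on 3R between 16448954 and 16452190, a span of 3237 bp. The run was singled out after its values were seen. Their scores were between 4.77 and 7.46, and the median gap between them was 169 bp. The largest gap, 1305 bp, separated the first peak from the others. Chained at 1 kb, that first peak fell in a group with the matched mouse peaks at 16447614, 16448388 and 16448632. That first peak had its deposited rank in common with those at 16448388 and 16448632. The peaks at 16450259 and 16450391 had another rank in common, and those from 16450901 to 16452189 yet another. Whether peaks with a rank in common were points of 1 called region was not tested, so the 10 peaks need not be 10 regions. The rabbit list had no peak in the run; its nearest peaks were 535 bp to the left (score 5.04) and 9338 bp to the right (score 2.53). The run supplied 3 of the 5 highest-scoring unmatched mouse peaks, at 16450391 (score 7.46), 16452189 (7.07) and 16450901 (6.68). The other two were on 3LHet at 2280615 (score 8.11) and on 2R at 17137448 (6.81), the latter 264 bp from a rabbit peak. Unmatched mouse peaks had a median score of 5.94 and matched ones 5.26, a difference that did not pass a permutation test (two-sided p = 0.29, 16 and 1622 peaks). The direction turned with the definition of a match. Matched peaks were higher by 1.28 where 200 bp windows had to overlap by at least 50% (permutation p = 0.0003), and by 0.45 where the deposited intervals had to overlap (permutation p = 0.042). Without the run, 6 unmatched mouse peaks were left, with a median of 4.63.

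**Figure D3:**
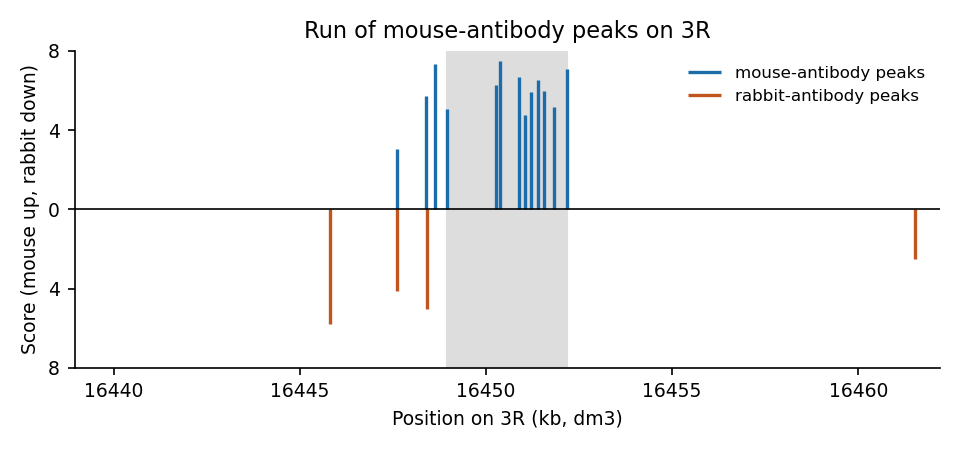
Peaks within 10 kb of the run of mouse-antibody peaks on 3R (grey band, 16448954 to 16452190, dm3): position in kb on the horizontal axis, score on the vertical axis, mouse peaks (blue) drawn upward and rabbit peaks (orange) downward. The band holds 10 mouse peaks and no rabbit peak.

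At the places both antibodies marked, stronger mouse peaks were paired with stronger rabbit peaks. Over 1607 one-to-one pairs the scores correlated with a Pearson r of 0.72 on the log scale and a Spearman rho of 0.72 (both permutation p = 1e-05, the smallest the resamples allow). This is a correlation across peaks of 2 libraries, not across samples. The authors' numbering correlated over the same pairs with a Spearman rho of 0.75.

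**Figure D4:**
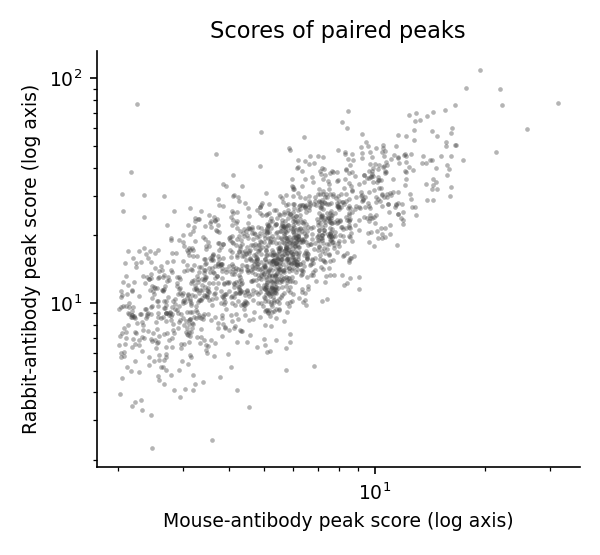
Each point is 1 of the 1607 one-to-one pairs of peaks within 250 bp, with the score in the mouse-antibody list (horizontal, log axis) against that in the rabbit-antibody list (vertical, log axis); scores have no stated unit. The points rise together (Spearman rho 0.72).

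The X chromosome held fewer of the mouse than of the rabbit peaks. It carried 183 mouse peaks, or 11.2% (9.69 to 12.8%), and 2033 rabbit peaks, or 16.7% (16.1 to 17.4%), an odds ratio of 0.63 (Fisher's exact test, adjusted p = 2.1e-08). In peaks per megabase, X had 8.17 mouse and 90.7 rabbit peaks, while 2R had 18.2 and 119 and 2L 12.3 and 89.6. The shares of 2R (Fisher's exact test, odds ratio 1.18, adjusted p = 0.031) and 3R (1.15, adjusted p = 0.045) were higher in the mouse list. Neither passed Fisher's exact test over the peaks outside X, where the odds ratios were 1.09 and 1.06 (adjusted p = 0.41 and 0.43). Arms 2L, 3L and 4 and the heterochromatic sequences did not pass the test, with adjusted p from 0.33 to 0.74. With the lists at equal length by score, the X share was 15.8% (14.1 to 17.7%) of the rabbit list and the odds ratio was 0.67 (Fisher's exact test, adjusted p = 0.00085). At that length the odds ratio was 1.21 for 2R (Fisher's exact test, adjusted p = 0.098) and 0.99 for 3R, neither past the test. That of 2R passed Fisher's exact test over groups of peaks (1.22, adjusted p = 0.015) and at equal lengths by numbering (1.25, adjusted p = 0.034). At equal lengths by numbering the X share of the rabbit list was 14.4% (12.7 to 16.2%) and the odds ratio of X was 0.75 (Fisher's exact test, adjusted p = 0.034). Rabbit peaks on X were matched less often, 202 of 2033 or 9.94% (8.67 to 11.3%), than those on the autosomes, 1548 of 10096 or 15.3%. This largely restates the lower X share, since nearly every mouse peak had a rabbit peak. Fisher's exact test took the lists as independent, although most mouse peaks lay at places of the rabbit list.

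**Figure D5:**
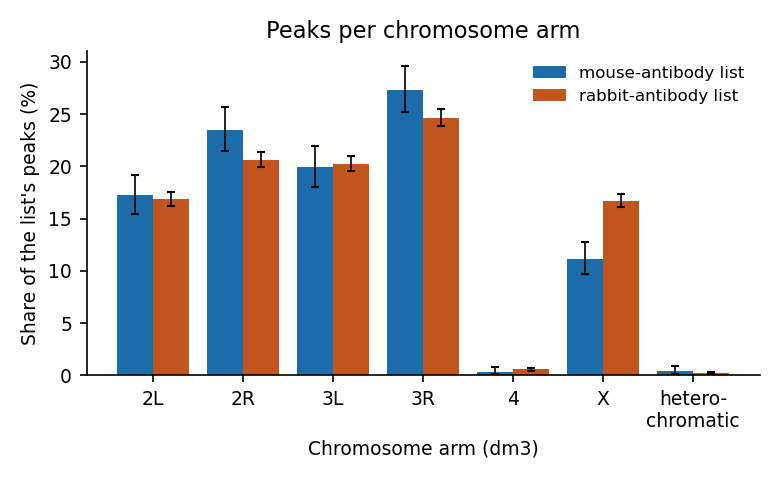
Share of each list's peaks (vertical axis, percent) on each arm of the dm3 build and on its heterochromatic sequences together, for the mouse-antibody list (blue) and the rabbit-antibody list (orange), with exact 95% intervals. X holds 11.2% of the mouse and 16.7% of the rabbit peaks.

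Peaks of both antibodies were unevenly spread over 100 kb windows. Among 100 kb windows, the fullest for the rabbit antibody was 3R from 12000001 to 12100000, with 47 peaks, 5 of which had a mouse partner. Next came 2R from 20800001 to 20900000 with 40, 3L from 21000001 to 21100000 with 38, 3R from 17400001 to 17500000 with 37 and 2R from 9800001 to 9900000 with 33. The fullest mouse window, 3R from 16400001 to 16500000 with 14 peaks, contained the unmatched run. The others were 2R from 3900001 to 4000000 with 11, 3L from 19600001 to 19700000 with 9, and 2R from 20800001 to 20900000 and 3R from 4600001 to 4700000 with 8 each, and every mouse peak in these 4 windows had a rabbit partner. The window on 2R from 20800001 was thus among the 5 fullest in both lists. The variance-to-mean ratio of peaks per window was 2.01 for the mouse and 5.41 for the rabbit list, against 1.16 and 1.76 for uniform placements (permutation p = 0.001 for both, the smallest 1000 placements allow). The ratio counts single peaks and was not computed over groups of peaks. It therefore does not separate close groups of peaks from crowding over wider regions. Of 1285 windows, 714 had peaks of both antibodies, 442 of the rabbit antibody alone and 1 of the mouse antibody alone.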

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

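The tests of a filter, of lower sensitivity (with the ranges it uses), of the heterochromatic share, of list length, of chance scatter and of the shares outside X were chosen only after the result was seen. The X share of peaks differed between the antibodies by Fisher's exact test, with an odds ratio of 0.63 (mouse over rabbit). By the same test the 2R share (odds ratio 1.18) and the 3R share (1.15) differed too. Over the peaks outside X these odds ratios were 1.09 and 1.06, and neither passed Fisher's exact test (adjusted p = 0.41 and 0.43). At equal lengths by score that of 3R was 0.99.

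The lower X share in the mouse list was not a matter of list length alone, since the rabbit list at the length of the mouse list had an X share of 15.8%, above the interval of the mouse share (9.69 to 12.8%). Lower coverage of X, which male embryos carry as a single copy, stays open. If it acted on weak peaks, the X to autosome odds ratio of a mouse match would lie near 1 among the top 10% of rabbit peaks by score, but it was 0.48 (0.35 to 0.65) there and 0.62 (0.51 to 0.75) over the others. That test took the autosomal peaks of the top 10% to be nearly all matched, but 59.4% were, so a coverage effect had room to act there too and the value does not decide, a reason found after the result was seen. A difference between the antibodies in what they bind on X was not tested.

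Nearly every mouse peak had a rabbit peak, yet most of the strongest rabbit peaks had no mouse peak. The density of rabbit peaks is argued against, since no circular shift matched more than 116 mouse peaks. A filter of the mouse list to places within 500 bp of a rabbit peak is argued against by 13 mouse peaks beyond that distance. Of these, 10 lay in the run on 3R and 3 elsewhere. A filter at a wider distance stays open, as 99.9% of mouse peaks lay within 5000 bp of a rabbit peak. A mouse library that was only less sensitive would have matched the strongest rabbit peaks first. By score this was not seen: 24.6% of the top 1% were matched. Peaks between 5% and 10% by score were matched more often than those between 1% and 2% (Fisher's exact test, odds ratio 1.78, p = 0.0042). By numbering, 8.20% of the first 1% were matched and the same odds ratio was 1.80 (Fisher's exact test, p = 0.018). The numbering has no stated basis, and scores in its first 1% ran from 2.0 to 233, so its values do not decide. It followed the deposited rank closely (Spearman correlation 0.96 in the rabbit list) and the score order less so (0.50). What the score measures is not stated either, so the values by score argue against lower sensitivity alone only if the score measures strength. Below the top 10% lower sensitivity may hold, the matched share rising beyond both intervals at 0 of 9 steps in either order. Heterochromatic sequences held 2.17% (0.26 to 7.63%) of the 92 unmatched peaks in the top 1%, and binding seen by the rabbit antibody alone, on or off target, and background that the IgG library would show stay open and were not tested, as that library was not analysed here.

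A run of 10 mouse peaks within 4 kb on 3R had no rabbit peak. Peaks of the run had deposited ranks in common, so they need not be 10 separate regions. Chance scatter stays open: random draws of 13 mouse peaks put at most 3 within 4 kb (10000 draws, permutation p = 0.0001, the smallest they can give), but the 10 peaks had 1 nearest rabbit peak in common and so were not matched or unmatched independently, as the draws assume. Ordinary crowding stays open as well: the rabbit list held 0 runs as dense whose peaks lay over 500 bp from any mouse peak, but it held 3 as dense in all, too few to decide. Binding that the mouse antibody alone detected, and DNA of this region introduced into the mouse library from another source, were not tested.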

How the results depend on the processing

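The settings by numbering, within 500 bp, over groups of peaks, without the run on 3R and outside X were chosen after seeing the data. Of 56 alternative values for 11 results, 36 stayed on the same side of their threshold and within 1.5 times the reported value. Asking the deposited 2 bp intervals to overlap left 8.18% of mouse and 1.10% of rabbit peaks shared, by construction. At equal list lengths by score the shares were 55.6% and 55.5%, and the median distance was 35 bp. At equal lengths by the authors' numbering the shares were 25.2% and 26.8%, and the median distance was 12991 bp. These shares stayed above the shifts (permutation p = 0.001), and the distances below them. The score difference between shared and unshared mouse peaks (-0.68) turned to 1.28 (permutation p = 0.0003) with 200 bp windows overlapping by at least 50%, to 0.45 (permutation p = 0.042) with the deposited intervals, and to 0.64 without the run on 3R; so its direction rests on the run and on the distance chosen. The odds ratio of 2R was 1.19 in the upper 50% of each list by score, 1.21 at equal lengths by score and 1.09 outside X, and none of these passed the test after adjustment, while it passed Fisher's exact test over groups of peaks (1.22, adjusted p = 0.015) and at equal lengths by numbering (1.25, adjusted p = 0.034). That of 3R was 1.15 in the upper 50%, 1.11 over groups of peaks and 1.06 both outside X and at equal lengths by numbering, none past the test, and 0.99 at equal lengths by score. The cause was not tested, except that the shares outside X cannot be raised by the lower X share. The variance-to-mean ratio of the upper 50% of the rabbit list was 3.2, where fewer peaks enter. No paired analysis was possible because each antibody has 1 library, and no replicate could be left out. The settings meant for peak width, genomic features, motif and gene lists were not run. Read depth is unknown, so the length of each list, and with it the share of rabbit peaks matched, cannot be corrected for it.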

Other observations

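Many rabbit peaks came in close groups, and the tests and the places named in this part were chosen only after the lists had been seen. Chained at gaps of up to 1 kb, 53.2% of rabbit peaks and 20.2% of mouse peaks had a neighbour in their own list. The rabbit list was 7.42 times as long and no chance share was computed, so these shares do not compare grouping between the antibodies. Peaks could share a deposited rank, with 6559 ranks for 12158 rabbit peaks and 909 for 1638 mouse peaks. Whether peaks of a group were points of 1 called region was not tested. The largest rabbit group lay on 2L between 12002211 and 12007499 and held 16 peaks, 3 of them with a mouse partner. Groups of 12 peaks lay on 2L from 15908921 to 15913662 and on 2R from 19756151 to 19761758, and a group of 11 on 2R from 7515717 to 7521113. A mouse partner was found for 11.1% (10.3 to 11.9%) of the 5687 lone rabbit peaks, 25.7% of the 1590 pairs and 72.7% (59.0 to 83.9%) of the 55 groups of 6 or more, against 0.68%, 1.18% and 3.56% after circular shifts. Among groups in the upper part of the list by best score (at or above the 75th percentile), 74.9% (68.1 to 80.9%) of the 191 groups of 4 or more were matched and 41.5% (38.5 to 44.4%) of the 1112 lone peaks (Fisher's exact test, odds ratio 4.21, p = 7.1e-18), with median best scores of 19.4 and 18.9. A group counted as matched where any mouse peak group lay within 250 bp of its span, so larger groups had more chances of a match. These shares therefore do not show that a grouped peak was matched more often than a lone one.

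The unmatched peaks of the rabbit top 1% were mostly lone and mostly more than 5 kb from any mouse peak. Of these 92 peaks, 61 (66.3%) had no rabbit neighbour within 1 kb and 87 lay more than 5 kb from the nearest mouse peak, with a median distance of 38637 bp. The mouse list is sparse (median gap 31434 bp) and no chance distance was computed, so these distances are not shown to exceed those of random places. Of the 30 matched peaks in the top 1%, 12 (40.0%) were lone. Median scores were 68.1 and 64.2.

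On the heterochromatic sequences, the mouse peak on XHet at 50416 (score 12) had a rabbit peak 6 bp away, and that on 3RHet at 2471431 (score 10) had one 26 bp away. The mouse peak on 3LHet at 2280615 (score 8.11) lay 710363 bp from the nearest rabbit peak.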
